A study of Mus musculus with 8 samples.

How the data were processed

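Messenger RNA of mouse atria was measured by bulk RNA sequencing in 8 libraries. Per the labels' protocols, mice with floxed Chd4 alleles received an AAV9 vector on postnatal day 2, and the atria were later dissected and frozen. The vector carried Cre recombinase (KO, 4 libraries) or EGFP (control, 4 libraries) behind the promoter of Nppa, a gene of atrial muscle. Messenger RNA was selected by oligo-dT, per the same protocols. The age at collection, the floxed exons and the number of mice behind each library were not given in the sources used here.

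The authors' deposited table held whole-number read counts per gene, not normalised, with a column for each library. The submitters' processing notes named STAR, DESeq2 and the mouse build mm10, without versions. The counting step, its strand setting and the annotation release were not given in the sources used here. Columns were matched to samples by vector (Cre or GFP) and number. Of 54532 genes in the table, 33437 had any count and 54495 had their identifier in GENCODE M21, whose coordinates on GRCm38 (the assembly of mm10) are printed here. Symbols came from the deposited table, where 100 symbols stood on more than 1 gene identifier, so genes were handled by identifier.

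Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total count of 15, which left 18033 genes. Libraries were scaled by TMM factors, and KO was compared with control by the robust quasi-likelihood test with no covariate, on 6 residual degrees of freedom and a common dispersion of 0.0204. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Levels are CPM, counts scaled to 1e6 per library, on the TMM scale, given as mean ± SD over 4 libraries. Principal components used the 500 most variable genes on a log2 CPM scale with a prior count of 2. A count of 3 in a library corresponded to 0.0744 to 0.0885 CPM and served as the floor for a gene with 0 counts in a group. Such floors cover counting error only.

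The groups, tests, alternatives, the rule for named genes and 30 gene lists were set before the data were examined. The rule named 15 genes of atrial and cardiac function, among them Chd4 and Tbx5, then the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 1 CPM, a curated symbol and groups that did not overlap, and up to 4 members with the smallest p of each list. A few genes under this rule are not reported here by name, though they stayed in every fit, count and list test. Other genes are named where marked as chosen after their values were seen. Each list with at least 3 tested members was tested by camera, a test of a list against all other genes, with a preset correlation between genes of 0.01, and again with an estimated correlation. This gave 29 tested lists, over which p-values were adjusted. Counts "adjusted over the list alone" come from adjusting the p-values within the list.

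The edgeR test was tested on simulated data for the comparison of KO with control, with 200 of 18033 genes changed 1.5-fold to 4-fold. In the same data 20 further genes were moved by 0.5 on the log2 scale and also counted as changed. It recovered 49.3% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 92.4% of those changed 4-fold, and 15 of its 169 calls (8.9%) were unchanged genes, above the nominal 5%. In the same simulation DESeq2 1.42.0 recovered 59.7%, 79.1% and 92.4%, and 41 of its 204 calls (20.1%) were unchanged genes. limma-voom recovered 49.3%, 76.1% and 89.4%, with 7.9% unchanged genes among its calls. These shares depend on how many genes were changed, so they do not carry over to the real data, where edgeR called 5032 genes. A stop at 15% or more unchanged genes was first set for every tool; it was limited to edgeR after DESeq2 exceeded it. Among the same 18033 simulated genes camera returned 3.38e-20 for the 20 genes moved by 0.5 on the log2 scale and 0.405 for 20 unmoved genes. The simulated genes were drawn independently, so these values do not show how camera behaves on lists of correlated genes.

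Alternatives covered other scalings, DESeq2, limma-voom with quality weights, other filters, the replicate number as a block, each library left out in turn, controls 1 and 2 alone, controls 3 and 4 alone, Y-linked expression as a covariate, a minimum fold change, and for the lists fry, a test of a list by itself. Pairs of libraries within a group differed by 12.2 to 31 times the sampling noise (chi-square per degree of freedom), so no library was counted as a copy of another. The labels number the samples but do not say that they came from separate mice, so p-values measure the spread between these samples, which may be technical. Library name prefixes were never shared between KO and control, so a difference between prefixes and the group difference cannot be told apart. Exons of 44 of the 145 genes under the naming rule overlapped exons of another annotated gene, 36 of them on the opposite strand alone, so some of their reads may belong to the neighbour. Figures were drawn with Python 3.11.15.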

Results

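The data were read counts per gene from 8 atrial libraries of Chd4flox/flox mice, 4 from mice injected with AAV9:Nppa-Cre (KO) and 4 from mice injected with AAV9:Nppa-EGFP (control). Chd4 encodes an ATP-dependent remodeller of the NuRD complex, which couples nucleosome remodelling with histone deacetylation, and the title of the series places it with the transcription factor TBX5 in atrial cardiomyocytes. The comparison asked which atrial transcripts changed when Chd4 was removed after birth. All 8 libraries came from mice with the floxed alleles, and Cre was present in KO alone and EGFP in control alone. Effects of Cre itself or of EGFP therefore cannot be told apart from the loss of Chd4. Total counts were 34002292 to 38228982 in the KO libraries and 39804625 to 40588007 in the control libraries. Mitochondrially encoded transcripts took 9.53% to 11.2% of the counts. The first principal component held 60% of the variance and separated the groups, while the second held 20.3% and set KO 2 (-21.4) and control 2 (-30.4) apart from the other libraries (1.3 to 14.5).

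The targeted gene Chd4 (ENSMUSG00000063870, chromosome 6, 125095981 to 125130591 on GRCm38) fell in the KO atria. Its level was 185 ± 12.4 CPM (SD, n = 4) in KO and 292 ± 13.3 CPM (SD, n = 4) in control, a 1.58-fold decrease with a log2 fold change of -0.66 (SE 0.06, edgeR adjusted p = 1.86e-05). Single libraries held 169, 185, 187 and 200 CPM in KO and 278, 297, 284 and 308 CPM in control. The counts cover the whole gene in whole atria and do not separate the floxed exons or the cell types. Of 15 NuRD genes, 4 rose, 3 fell, the targeted Chd4 among them, and 8 were not called (5 and 3 adjusted over the list alone). Chd5, a paralog of Chd4 known mainly from neurons and testis, rose from 1.46 ± 0.46 to 32.6 ± 3.40 CPM, a 22.3-fold increase (adjusted p = 1.47e-07). Chd3, another paralog, rose 1.87-fold from 97.3 ± 5.47 to 182 ± 11.5 CPM (adjusted p = 1.73e-06), and the deacetylase Hdac1 rose 1.30-fold (adjusted p = 0.00239). The list had a median log2 fold change of 0.07 and a mean of 0.36, with Chd5 at 4.48. Camera called the list up with an adjusted p of 0.0331 (0.0617 without KO 1, and adjusted p = 0.526 with an estimated correlation).

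In all, 5032 of 18033 tested genes were called by edgeR, 2677 higher and 2355 lower in KO. The changes of at least 2-fold comprised 703 higher and 353 lower genes, and those of at least 4-fold 233 and 69. Of 14710 protein-coding genes tested, 2410 were higher and 2134 lower. Against controls 3 and 4 alone, 1700 genes were higher and 2034 lower, and against controls 1 and 2 alone 1843 and 1647. The Y-linked gene Ddx3y was at 0.86 and 0.71 CPM in controls 1 and 2 and at 105 and 106 CPM in controls 3 and 4. It was at 0.72 CPM in KO 2 and at 108 to 124 CPM in the other KO libraries. The control pairs also differed in library name prefix, so Y-linked expression and prefix cannot be told apart between them.

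**Figure D1:**
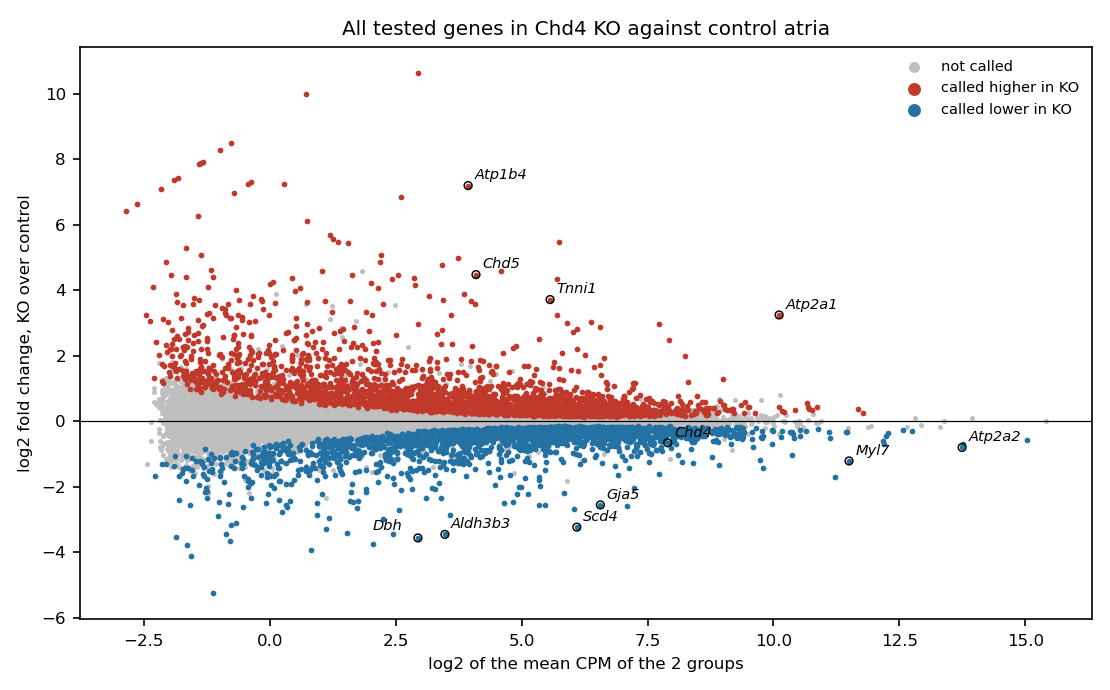
Each point is a tested gene, with the log2 of the mean CPM of both groups on the x axis and the log2 fold change of KO over control on the y axis, red for 2677 genes called higher, blue for 2355 called lower and grey for genes not called. Circles mark genes named in the text, and the fitted fold changes at the upper left belong to genes with few or no control counts and depend on the prior count.

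The most increased genes under the naming rule had mean levels of 0 to 2.35 CPM in control atria. Nat3, an arylamine N-acetyltransferase gene, had 488 counts over the KO libraries and 0 over the controls, so it was at least 42.3-fold higher against a floor of 3 counts per control library. Rhox2d, of a homeobox cluster with near-identical copies that can share reads, had 358 counts in KO and 2 in control. Atp1b4, a subunit gene of the Na,K-ATPase family, rose from 0.204 ± 0.173 to 30.4 ± 6.31 CPM (adjusted p = 7.91e-07), with a log2 fold change of 7.19 that was 7.95 without control 4. Tcfl5, a helix-loop-helix factor of male germ cells, rose with a log2 fold change of 6.84 that was 8.70 without control 4 (adjusted p = 1.22e-05). Snhg11, a small nucleolar RNA host gene annotated as protein-coding in GENCODE M21, rose 44.5-fold from 2.35 ± 1.59 to 105 ± 23.4 CPM (adjusted p = 0.000519). Further genes of this set, Kank4os, Epx, Urah and Kcnj14, rose 33.7-fold to 52-fold.

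The most decreased genes included enzymes and receptors. Esr2, the estrogen receptor beta gene, fell 15.2-fold from 3.30 ± 0.289 to 0.21 ± 0.175 CPM (adjusted p = 0.000179). Dbh, which encodes the enzyme that makes noradrenaline, fell 11.8-fold from 14.1 ± 1.77 to 1.20 ± 0.482 CPM (adjusted p = 1.84e-06). The neighbouring aldehyde dehydrogenase genes Aldh3b3 and Aldh3b2, paralogs that can share reads, fell 10.9-fold and 10.7-fold. Scd4, a stearoyl-CoA desaturase gene, fell 9.39-fold from 124 ± 47.1 to 13.2 ± 4.28 CPM (adjusted p = 0.00103). Gcgr, the glucagon receptor gene, had a log2 fold change of -3.30 that was -3.98 without KO 3, and Ntsr2, a neurotensin receptor gene, fell 7.24-fold. Golga7b, T2 and Armc2 fell 6.58-fold to 13.5-fold.

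Most genes of atrial identity fell in the KO atria. Of 19 such genes, 15 fell, 2 rose and 2 were not called (15 and 2 adjusted over the list alone), with a median log2 fold change of -0.51 (camera adjusted p = 3.56e-10, adjusted p = 0.296 with an estimated correlation). Tbx5, the transcription factor of atrial identity, fell 1.56-fold from 305 ± 7.49 to 195 ± 12 CPM (log2 fold change -0.64, SE 0.06, adjusted p = 1.24e-05). Myl7, the atrial myosin light chain, fell 2.31-fold from 4043 ± 247 to 1748 ± 180 CPM (adjusted p = 1.25e-06). Gja5, which encodes the gap junction protein connexin 40, fell 5.86-fold from 161 ± 43.6 to 27.5 ± 5.36 CPM (adjusted p = 0.000154). Nppa, the natriuretic peptide gene whose promoter drove the vectors, fell 1.62-fold from 17155 ± 918 to 10574 ± 1921 CPM (adjusted p = 0.000808). Sln, the sarcolipin gene, fell 1.31-fold (adjusted p = 0.00168), Dkk3 2.66-fold and Stard10 2.14-fold. Bmp10, an atrial growth factor gene, fell 1.25-fold (adjusted p = 0.0414), a call lost without any 1 of KO 2, KO 3, KO 4, control 1 or control 4 (adjusted p = 0.103 to 0.114).

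Nr2f2, a nuclear receptor gene of atrial identity, rose 1.28-fold (adjusted p = 0.0317), a call lost without control 1 (0.0871) or control 2 (0.0762) and against controls 3 and 4 alone (0.273). Of 10 ventricular genes, 3 rose, 1 fell and 6 were not called, the same counts as adjusted over the list alone. Their median was 0.23, their mean -0.01, and camera gave the direction up with an adjusted p of 0.728 (adjusted p = 0.893 with an estimated correlation). Fhl2 fell 1.79-fold and Kcnd2 rose 1.34-fold. Myl3, a ventricular and slow muscle light chain, rose 2.45-fold (adjusted p = 0.0208), a call lost without KO 1, control 2 or control 4 (adjusted p = 0.0579 to 0.0596). Myl2, the ventricular light chain, was at 26.4 ± 28 CPM in KO and 92.6 ± 117 CPM in control (adjusted p = 0.318), with 268 CPM in control 1. Beside these genes, markers of other cell types were higher, with a median log2 fold change of 0.20 for endothelial, 0.30 for fibroblast and 0.47 for epicardial markers.

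**Figure D2:**
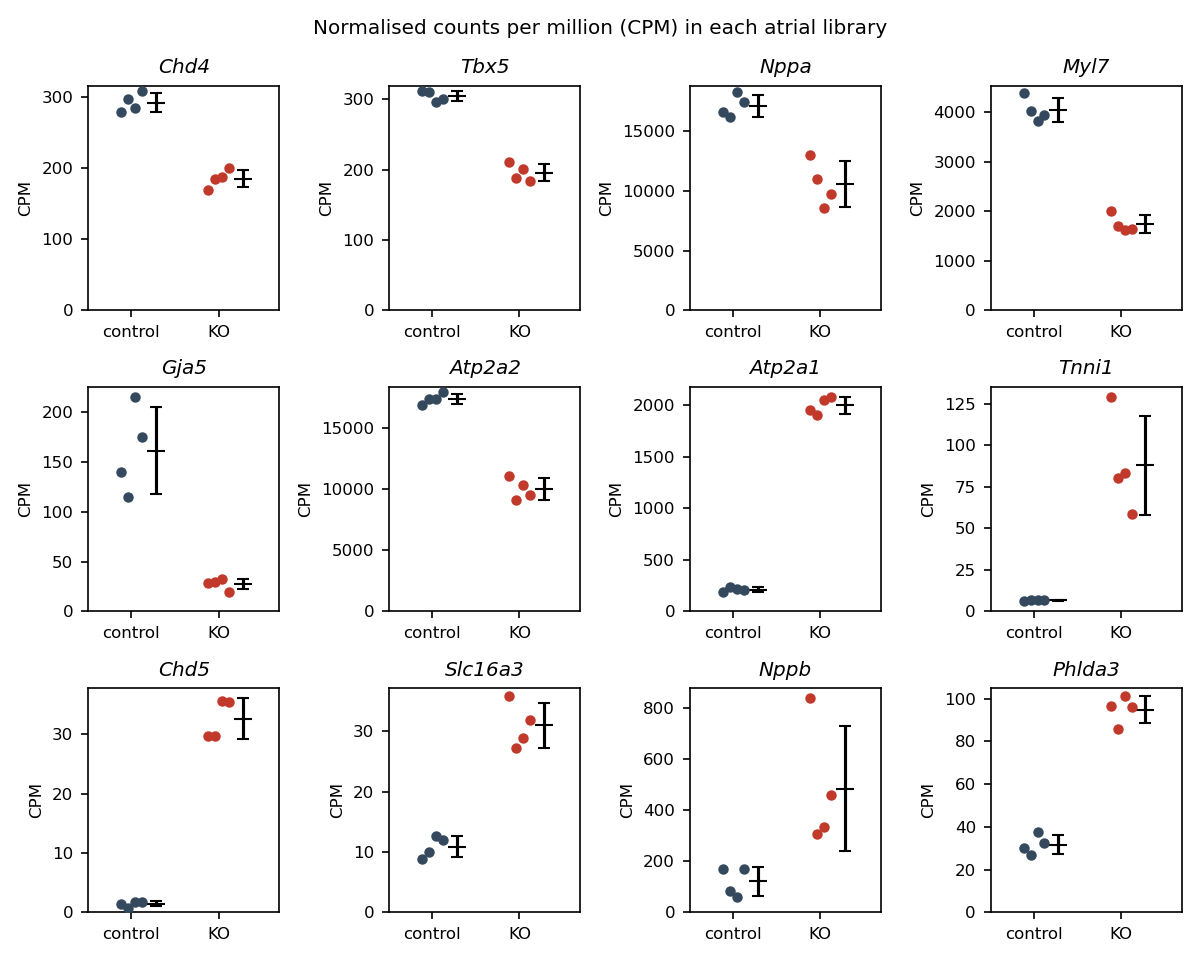
Each panel gives the CPM of a gene in the 4 control (dark) and 4 KO (red) libraries, with the mean and SD beside the points and the y axis from 0. Chd4, Tbx5, Nppa, Myl7, Gja5 and Atp2a2 were lower in every KO library than in every control library, and Atp2a1, Tnni1, Chd5, Slc16a3, Nppb and Phlda3 were higher.

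More genes of the cardiac sarcomere, the contractile unit, were called lower than higher in KO. Of 21, 12 fell, 1 rose and 8 were not called, the same counts as adjusted over the list alone (median log2 fold change -0.31, camera adjusted p = 0.000142, adjusted p = 0.526 with an estimated correlation). Myh6, the main myosin heavy chain of these atria at 40488 ± 2252 CPM in control, fell by 0.58 on the log2 scale to 26991 ± 2282 CPM (adjusted p = 0.000207). Myoz2 and Tpm1 fell by 0.68 and 0.60 on the log2 scale. Myh7, the slow myosin heavy chain, was at 229 ± 19.3 CPM in KO and 271 ± 57.4 CPM in control (adjusted p = 0.236), a difference called without control 3 (adjusted p = 0.00841) and against controls 1 and 2 alone (0.00521).

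A subset of skeletal muscle genes rose in every KO library while others did not. Of 23 tested genes of the skeletal muscle program, 6 rose, 1 fell and 16 were not called (7 and 3 adjusted over the list alone). Atp2a1, the calcium pump of fast skeletal muscle, rose 9.48-fold from 211 ± 22.3 to 2001 ± 81.5 CPM (log2 fold change 3.25, SE 0.08, adjusted p = 5.15e-10). The troponin I genes Tnni2 and Tnni1 rose 5.62-fold and 13.1-fold, to 410 ± 93.2 and 87.9 ± 29.6 CPM, and the calcium store gene Casq1 rose 4.08-fold. The median log2 fold change was -0.73 and the mean 0.12, while camera gave the direction up with an adjusted p of 0.00622 (adjusted p = 0.593 with an estimated correlation). Without KO 2 camera gave the direction down with an adjusted p of 0.24. Of 12 smooth muscle genes, 5 rose, 1 fell and 6 were not called (6 and 1 adjusted over the list alone), with Tpm2 up 2.32-fold to 443 ± 58.9 CPM and Tagln up 4.06-fold to 2.73 ± 0.251 CPM. Acta2, smooth muscle actin, named after its value was seen, fell 2.66-fold from 203 to 76.3 CPM (adjusted p = 0.0375), a call lost without any 1 of KO 1, KO 2, KO 3, KO 4, control 2 or control 4 (0.0535 to 0.0949), and Myh11 was at -0.54 on the log2 scale (adjusted p = 0.151). The smooth muscle list was called up with an adjusted p of 0.0284 (0.0645 without KO 4, 0.0651 without control 3, and adjusted p = 0.526 with an estimated correlation).

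**Figure D3:**
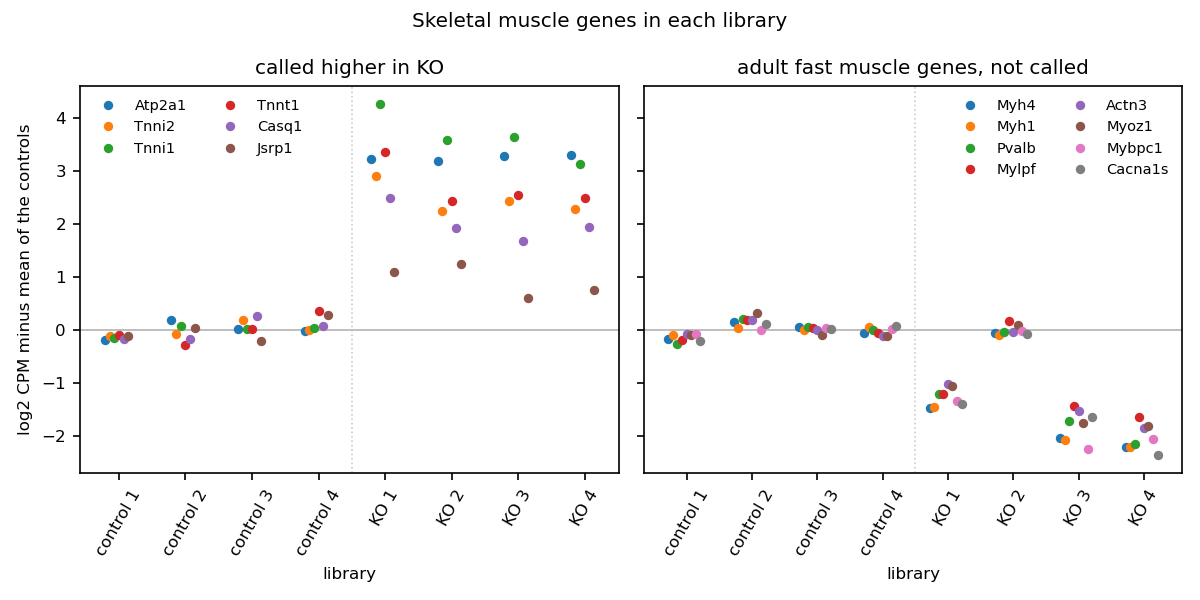
The y axis gives log2 CPM minus the mean of the 4 controls for each library on the x axis, for 6 skeletal muscle genes called higher in KO (left) and 8 adult fast muscle genes that were not called and were chosen after their values were seen (right, without Myh2, which was called lower). On the left, all 4 KO libraries lie above the controls, and on the right KO 2 lies with the controls while KO 1, KO 3 and KO 4 lie lower, as in Myh4 (327 CPM in KO 2 against 122, 82.3 and 73.6).

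Ion channel genes moved in both directions. Of 22 ion channel and gap junction genes, 6 rose, 7 fell and 9 were not called (7 and 7 adjusted over the list alone). Scn4b and Scn10a, which encode sodium channel subunits, rose 3.75-fold and 3.19-fold, and Kcnj2, of the inward-rectifier potassium current, fell 1.39-fold (adjusted p = 0.000121). The list had a median of 0.04 and camera called it up (adjusted p = 0.0478, adjusted p = 0.526 with an estimated correlation), a call lost without any 1 of KO 1, KO 3, control 1, control 2 or control 3 (0.0582 to 0.0995).

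Calcium handling genes moved in both directions as well. Of 18, 4 rose, 5 fell and 9 were not called (5 and 5 adjusted over the list alone). Atp2a2, the cardiac calcium pump, fell 1.74-fold from 17427 ± 419 to 10028 ± 893 CPM (log2 fold change -0.80, SE 0.07, adjusted p = 1.4e-05). Fkbp1b, which encodes a partner of the ryanodine receptor, rose 1.81-fold (adjusted p = 0.00115), while Trdn and Hrc fell 1.23-fold and 1.30-fold. Ryr2, the cardiac ryanodine receptor gene, fell 1.18-fold (adjusted p = 0.0261), a call lost without KO 2 (0.0789), control 1 (0.0577) or control 4 (0.0848). The median was 0.00, the mean 0.08, and camera gave the direction down with an adjusted p of 0.728 (adjusted p = 0.893 with an estimated correlation).

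Of 20 cardiac transcription factor genes, 8 fell, 2 rose and 10 were not called (10 and 3 adjusted over the list alone). Besides Tbx5, Tbx3 fell 1.91-fold (adjusted p = 0.00155), Srf 1.46-fold (adjusted p = 0.00462) and Meis1 1.37-fold (adjusted p = 0.000536). The median was -0.23 and camera called the list down (adjusted p = 0.0331, adjusted p = 0.527 with an estimated correlation), a call lost without control 3 (0.0651) or control 4 (0.0521). Markers of other cell types were higher beside this fall, and a changed share of cardiomyocyte RNA was not tested for this list.

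Most genes of oxidative phosphorylation, which encode the respiratory chain, fell. Of 44, 35 fell, 0 rose and 9 were not called by edgeR (41 fell adjusted over the list alone), with a median of -0.37 (camera adjusted p = 1.47e-13, adjusted p = 0.526 with an estimated correlation). Ndufa8 fell 1.69-fold, Cox7a1 1.67-fold, Cox8b 1.56-fold and Cox5b 1.54-fold, from 406 ± 20.3 to 264 ± 22.7 CPM for Cox5b (adjusted p = 6.09e-05). Beside this fall, the means of the endothelial, fibroblast, macrophage and epicardial marker lists were higher by 0.22, 0.23, 0.36 and 0.57 on the log2 scale. Of 20 genes of fatty acid oxidation, 4 fell, 2 rose and 14 were not called, the same counts as adjusted over the list alone (median -0.08, camera adjusted p = 0.269, down, adjusted p = 0.806 with an estimated correlation). Among these, Ppara and Fabp3 fell 1.44-fold and 1.41-fold. Of 16 glycolysis genes, 5 rose, 2 fell and 9 were not called, again the same counts as adjusted over the list alone. The lactate transporter gene Slc16a3 rose 2.84-fold from 10.9 ± 1.75 to 30.9 ± 3.76 CPM (adjusted p = 5.37e-06). Of the phosphofructokinase genes, Pfkp and Pfkl rose by 0.97 and 0.58 on the log2 scale while Pfkm, the muscle form, fell by 0.54. The glycolysis list was not called (median 0.08, camera adjusted p = 0.0818, up, adjusted p = 0.688 with an estimated correlation), but was called without KO 2, KO 3 or KO 4 (0.0415 to 0.0491).

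Most targets of the p53 pathway, which responds to DNA damage, rose. Of 14, 11 rose, 0 fell and 3 were not called by edgeR (11 higher and 1 lower adjusted over the list alone), with a median of 0.55 (camera adjusted p = 2.81e-09). This was the only of the 29 lists called with an estimated correlation (adjusted p = 0.0282). Phlda3 rose 2.99-fold from 31.7 ± 4.59 to 94.8 ± 6.38 CPM (adjusted p = 6.94e-07) and Eda2r 2.71-fold from 6.21 ± 0.71 to 16.8 ± 1.31 CPM (adjusted p = 1.98e-06). Btg2 rose 1.86-fold, and Bax, a gene of apoptosis whose exons overlap a predicted gene on the same strand, rose 1.52-fold.

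Of 12 genes of the integrated stress response, 7 rose, 2 fell and 3 were not called, the same counts as adjusted over the list alone. Sesn2 rose 2.00-fold, Mthfd2 1.51-fold and Atf5 1.36-fold, while Aldh1l2 fell 2.33-fold (median 0.46, camera adjusted p = 0.317, up, adjusted p = 0.593 with an estimated correlation, 0.0338 by fry). Of 17 interferon response genes, 5 rose, 0 fell and 12 were not called by edgeR (6 higher adjusted over the list alone), and Ifit3 rose 2.06-fold from 6.31 ± 1.73 to 13.0 ± 1.11 CPM (adjusted p = 0.00094). The interferon list had a median of 0.37 and was called up (camera adjusted p = 0.0331, adjusted p = 0.593 with an estimated correlation), a call lost without KO 4 (0.0769), control 2 (0.0711) or control 4 (0.0521) and by fry (0.0523). Of 15 cardiac stress genes, 4 rose, 1 fell and 10 were not called, the same counts as adjusted over the list alone. Gdf15 rose 3.61-fold from 1.33 ± 0.24 to 4.82 ± 0.702 CPM (adjusted p = 1.97e-05) and Cryab fell 1.33-fold. Nppb, the B-type natriuretic peptide gene, rose 3.99-fold from 121 ± 57.2 to 484 ± 245 CPM (adjusted p = 0.0277), a call lost without KO 4 (0.0587), control 2 (0.0721) or control 3 (0.0527), with Y-linked expression as a covariate (0.0657) and with no filter on low counts (0.0503). The stress list had a median of 0.32 (camera adjusted p = 0.0746, up, adjusted p = 0.593 with an estimated correlation), and it was called without KO 2, KO 3 or control 1 (0.025 to 0.0464), with no filter on low counts (0.0156) and against controls 3 and 4 alone (0.0369).

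Of 22 cell cycle genes, 3 rose, 0 fell and 19 were not called by edgeR (1 higher adjusted over the list alone), among them Mcm3, up 1.32-fold (adjusted p = 0.012). The cell cycle list had a median of 0.37 (camera adjusted p = 0.0729, up, adjusted p = 0.688 with an estimated correlation), and was called without KO 3 (0.0456), KO 4 (0.0279) or control 3 (0.00439). Of 11 immediate early and heat shock genes, 3 rose, 1 fell and 7 were not called, the same counts as adjusted over the list alone (median 0.18, camera adjusted p = 0.318, up, adjusted p = 0.688 with an estimated correlation). Atf3 rose 3.32-fold from 9.42 ± 0.899 to 31.3 ± 14.5 CPM (adjusted p = 0.00359), and Jun 1.35-fold. Of 10 germline genes 2 passed the filter, too few for camera, with Sycp3 at 1.86 ± 0.255 CPM in KO and 1.58 ± 0.533 CPM in control (adjusted p = 0.523). The other, Dazl, rose 2.32-fold (adjusted p = 0.0228), a call lost without KO 2, KO 4, control 2 or control 4 (0.0528 to 0.069). Its list counts were 1 higher and 0 lower by edgeR, also adjusted over the list alone.

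In the epicardial, endothelial, fibroblast, macrophage and lymphocyte lists more markers were called higher than lower in KO. Of 10 epicardial and mesothelial markers, 8 rose, 0 fell and 2 were not called by edgeR (9 higher adjusted over the list alone, median 0.47, camera adjusted p = 0.000502, adjusted p = 0.526 with an estimated correlation). Krt18 rose 2.22-fold and Bnc1 1.64-fold. Of 13 endothelial markers, 8 rose, 1 fell and 4 were not called (9 and 1 adjusted over the list alone), with Eng up 1.35-fold and Npr3 up 1.40-fold. The endothelial median was 0.20 (camera adjusted p = 0.0284, 0.0558 without control 3, and adjusted p = 0.526 with an estimated correlation). Of 13 fibroblast markers, 6 rose, 0 fell and 7 were not called by edgeR (7 higher and 1 lower adjusted over the list alone), with Tcf21 up 1.52-fold and Col3a1 up 1.29-fold. The fibroblast median was 0.30 (camera adjusted p = 0.0467, adjusted p = 0.526 with an estimated correlation), and the call was lost without any 1 of KO 2, KO 4, control 2, control 3 or control 4 (0.0521 to 0.074). Of 21 genes of matrix remodelling, 11 rose, 0 fell and 10 were not called by edgeR, also adjusted over the list alone (median 0.46, camera adjusted p = 9.59e-06, adjusted p = 0.526 with an estimated correlation). The growth factor gene Tgfb2 rose 2.25-fold, Sfrp2 1.98-fold and Comp 1.85-fold.

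Of 16 macrophage and monocyte markers, 5 rose, 0 fell and 11 were not called by edgeR (9 higher adjusted over the list alone), with Adgre1 up 1.43-fold and C1qb up 1.30-fold. The macrophage median was 0.38 (camera adjusted p = 0.0316, 0.0855 without KO 1, 0.0711 without control 2, 0.0592 by fry, and adjusted p = 0.593 with an estimated correlation). Of 13 lymphocyte markers, 3 rose, 0 fell and 10 were not called by edgeR (4 higher adjusted over the list alone). The T cell receptor complex gene Cd3e rose 2.97-fold from 1.31 ± 0.862 to 3.91 ± 1.35 CPM (adjusted p = 0.0239), a call lost without KO 2 (0.0607) or control 4 (0.0522). The lymphocyte median was 1.29 (camera adjusted p = 0.0467, adjusted p = 0.593 with an estimated correlation), and the call was lost without any 1 of KO 1, KO 2, control 2 or control 4 (0.0582 to 0.0711). Of 4 tested lung and thymus markers, 1 rose, 0 fell and 3 were not called by edgeR (3 higher adjusted over the list alone, median 1.64, camera adjusted p = 0.0818, up, adjusted p = 0.593 with an estimated correlation), and the list was called without control 3 (0.00439) and by fry (0.0366). All 4 were thymus or T cell genes (Cd8b1, Rag2, Dntt and Rag1), and no lung gene passed the filter. The called gene was Cd8b1 (adjusted p = 0.04996). Its call was lost without any 1 of KO 1, KO 2, KO 3, KO 4, control 1, control 2 or control 4 (0.0619 to 0.121). The thymocyte gene Rag1 was at 41.7 ± 17.1 CPM in KO and 14.5 ± 11.6 CPM in control (adjusted p = 0.142, 0.0465 without control 3, 0.0437 by limma-voom).

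Of 6 adipocyte markers, 0 rose, 1 fell and 5 were not called by edgeR, also adjusted over the list alone. Their median was 2.98 and mean 2.06, with Cfd at 39.3 CPM in KO 4 and 0.381 to 1.18 CPM in the other KO libraries, while camera gave the direction down (adjusted p = 0.818, adjusted p = 0.895 with an estimated correlation), and Plin4 fell 1.67-fold (adjusted p = 0.0161, lost at 0.0679 with no filter on low counts). Of 10 neuron and Schwann cell markers, Dbh fell and 9 were not called by edgeR, also adjusted over the list alone. Dbh was at 13.4 CPM in control 2 and 12.1 to 16.1 CPM in the other controls. Snap25 and Syt1 were at 0 CPM in control 2, so Dbh did not follow these neuronal transcripts there. The neuronal list had a median of -0.13 (camera adjusted p = 0.0861, down, adjusted p = 0.593 with an estimated correlation), and was called without KO 3 (0.0425), KO 4 (0.0491) or control 2 (0.0284), with no filter on low counts (0.0468), with Y-linked expression as a covariate (0.0463) and against controls 3 and 4 alone (0.0307). It was also called (0.00673) without both KO 2 and control 2, an alternative chosen after seeing the data. Of 6 erythroid markers, 1 fell and 5 were not called, also adjusted over the list alone (median -0.44, camera adjusted p = 0.197, down, adjusted p = 0.688 with an estimated correlation). The called gene, Hba-a2 (adjusted p = 0.0309), is a near-identical copy of Hba-a1 and its reads are uncertain, and its call was lost without any 1 of KO 1, KO 3, control 1, control 3 or control 4 (0.0626 to 0.0784). Of 4 Y-linked genes 0 were called by edgeR, with Ddx3y at 0.72 to 124 CPM in KO and 0.71 to 106 CPM in control libraries (list median 0.58, camera adjusted p = 0.728, up, adjusted p = 0.893 with an estimated correlation).

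**Figure D4:**
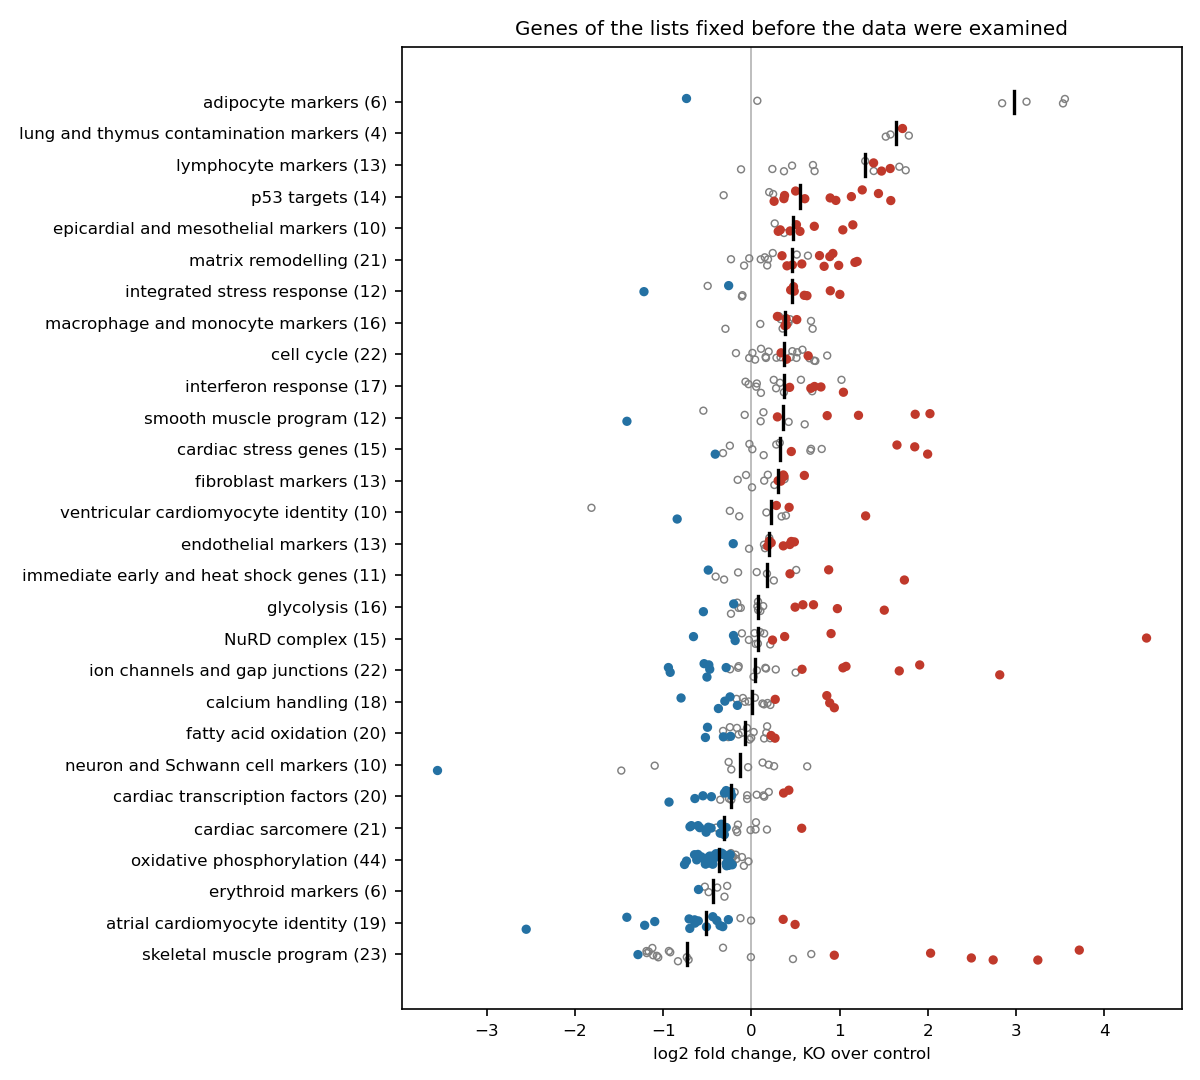
Each point is a tested gene of a list fixed in advance, at its log2 fold change of KO over control on the x axis, filled red or blue where called higher or lower and open where not called, with a black bar at the list median and the number of genes in brackets. The atrial identity (median -0.51) and oxidative phosphorylation (-0.37) lists lie to the left and the p53 targets (0.55) to the right, and the Y-linked and germline lists are left out.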

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

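The tests of the muscle RNA ratio, of thymus RNA and of the share of cardiomyocytes were chosen after the result was seen, as were the lists of further muscle, fast muscle, thymocyte and effector T cell genes. For skeletal muscle tissue RNA and effector T cells the bounds were written after the rise was seen but before the further genes, Nkg7 excepted, were looked at, and the sample splits were set before their results.

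Of the 35 splits of the 8 libraries into 4 and 4, only the real one gave 5032 calls, and the highest of the others gave 1. This argues against a chance assignment of the libraries for the number of called genes, within the limit of 35 splits. The other splits mix KO and control libraries, and a difference between library name prefixes would give the same result. For the excess of 62 near-silent genes called higher over lower the splits decided nothing, since the others called at most 1 gene and could reach no such excess.

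The rise of Atp2a1, Tnni2, Tnni1, Tnnt1, Casq1 and Jsrp1 could come from skeletal muscle tissue in the KO dissections. Such tissue would bring its other transcripts, but 12 further muscle genes had a median log2 fold change of -0.11 (2 called higher, 3 lower). The highest was Tmod4 at 0.70, below the 0.94 of Jsrp1. Some of the 12 were high in control atria (Pgam2 at 348 to 482 CPM, Xirp1 at 193 to 231), which could hide added muscle RNA in this median. Myh4 was at 73.6 to 122 CPM in KO 1, KO 3 and KO 4 and 327 in KO 2, against 301 to 378 in the controls. The median and the Myh4 levels argue against muscle tissue RNA as the source of the rise, the median less strongly. The lower adult fast muscle genes in KO 1, KO 3 and KO 4 stay open, because the test of a fixed ratio between them (0.147) ran on 8 genes picked after their values were seen and left out Myh2, which was called lower (1.68 to 2.48 CPM in these libraries, 6.08 in KO 2 and 6.10 to 8.56 in the controls, a call lost without any 1 of KO 1, KO 3, control 1, control 3 or control 4 at 0.0571 to 0.0716). Induction in Chd4-deficient cells remains a hypothesis for the 6 genes, and reads shared between paralogs were not tested.

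T cell genes (Cd3e, Cd3d, Cd3g, Trbc2) were higher in KO by 1.55 on the log2 scale (SE 0.52, exact permutation p = 0.057) and thymocyte genes (Rag1, Rag2, Dntt) by 1.97 (SE 0.73, exact permutation p = 0.057), both two-sided. Among 11 thymocyte genes 2 were called higher (median 1.43), with Rag1 at 26.8 to 66.2 CPM in KO and 3.33 to 30.6 in control. The log2 ratio of T cell to thymocyte genes differed between groups by -0.42 (SE 0.29, exact permutation p = 0.114), within the 0.5 set for thymus RNA though 2 standard errors reach past it, and lay between -1.17 and -0.72 in all libraries except control 1 (0.21). Effector T cell and NK cell genes, of which 5 were tested and none was called by edgeR, had a median of 0.37, between the bounds of 0.3 against and 0.7 for effector cells. More T cells without thymocytes would raise the ratio of T cell to thymocyte genes. It lay at -1.17 to -0.99 in KO and -1.14 to 0.21 in control, which argues against such T cells as the whole source. The spread of the ratio is wide through control 1, where the T cell and thymocyte genes averaged -0.13 and -0.34 log2 CPM. Thymus tissue in the dissections and a part from T cells in the KO atria cannot be told apart, because the effector genes lie between their bounds.

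A lower share of cardiomyocyte RNA could raise markers of other cells and lower sarcomere genes alike, but 11 of 21 sarcomere genes lay over 2 standard errors from their median of -0.31 (about 1 by chance), from -0.70 to 0.57. By the same measure 11 of 19 atrial identity genes lay apart from their median of -0.51 (about 1 by chance), from -2.55 to 0.49. The first test of the other cell types was undecided: the mean rises of 4 marker lists differed by at most 0.36 (epicardial less endothelial, SE 0.16, exact permutation p = 0.057). A further test, added because the first was undecided, found 16 of 52 single markers over 2 standard errors from their common median of 0.34 (about 2.6 by chance), from -0.29 to 1.15. The sarcomere and atrial identity values argue against a lower share of cardiomyocyte RNA as the whole cause of the fall of these genes. For the atrial list this holds only for genes restricted to cardiomyocytes, which was not tested. The marker values argue against a common dilution as the whole cause of their rise, but not against shares that changed differently between cell types. A part of each, a response within each cell type, and a changed share for the oxidative phosphorylation genes stay open.

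Of 294 tests for a library far from its group, 20 stood out where chance gives 14.7, by the Dixon ratio, the gap to the nearest library over the group's range. Adipocyte genes stood out in KO 4, where Cfd was at 39.3 CPM against 0.381 to 1.18 (ratio 0.979), Cidec at 16.5 (0.957) and Plin1 at 17.2 (0.936), with Atf3 at 52.7 CPM against 20.7 to 26.0 (0.835). In KO 2, Xist was at 395 CPM against 0.266 to 30.4 (0.924), Ddx3y at 0.72 (0.87), Kdm5d at 0.199 (0.972) and Uty at 0.223 (0.936). In KO 1, Nr2f2 was at 99.2 CPM (0.862), Cryab at 633 (0.84) and Fabp3 at 587 (0.903). Scn10a was at 50.8 CPM in KO 3 (0.906) and at 21.1 in control 4 (0.922), and Tcfl5 at 0.331 in control 4 (0.848). In control 1, Myl2 was at 268 CPM against 19.5 to 44.9 (0.898) and Sesn2 at 5.12 (0.883). In control 2, Hbb-bs was at 510 CPM (0.871), Cox5b at 375 (0.859) and C1qc at 32.4 (0.869), and Fkbp1b was at 2.78 in control 3 (0.872).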

How the results depend on the processing

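The alternatives without both KO 2 and control 2 were chosen after seeing the data; the others were planned. Chd4 was called lower under every alternative scaling, tool, filter and choice of libraries, with -0.69 to -0.62 when single libraries were left out. No gene of the 5032 called changed direction under any alternative, and no alternative moved the median of all genes by over 0.028. Calls higher and lower numbered 2838 and 2718 by DESeq2, 3235 and 2873 by limma-voom, 2032 to 2687 and 1877 to 2614 with single libraries left out, and 2013 and 1971 without KO 2 and control 2. With the replicate number as a block they numbered 2474 and 2283. Same-numbered libraries deviated together with correlations of -0.02, 0.30, -0.06 and 0.10, and only number 2 matched best with itself. Pairing by number was thus not seen for the other numbers, but these correlations cannot exclude it. With this block the stress (0.000954), neuronal (0.0334) and lung and thymus (0.0348) lists were also called, and Nr2f2 (0.067), Plin4 (0.0757), Hba-a2 (0.124), Plk1 (0.0724), Dazl (0.0566) and Egr1 (0.0546) lost their calls. Of the named genes 12 lost their call with no filter on low counts (among them Nppb at 0.0503, Myl3 at 0.0513, Bmp10 at 0.063, Plin4 at 0.0679, Cd3e at 0.106 and Hba-a2 at 0.127), 6 with the Y-linked covariate (among them Nppb at 0.0657 and Hba-a2 at 0.0525), 22 against controls 1 and 2 (among them Kcnd2 at 0.1 and Atf3 at 0.0612), 21 against controls 3 and 4 (among them Col3a1 at 0.0781, Mcm3 at 0.0962 and Atf3 at 0.0739), and 20 without KO 2 and control 2. With no filter the stress (0.0156), neuronal (0.0468), glycolysis (0.014) and cell cycle (0.0111) lists were also called, and with the filter on CPM the ion channel, transcription factor, fibroblast and interferon lists lost their calls (0.0561 to 0.0623). Against controls 1 and 2 the transcription factor (0.133), fibroblast (0.097) and endothelial (0.11) lists lost their calls, and the lung and thymus (0.00828), fatty acid (0.0196), glycolysis (0.0457) and cell cycle (3.57e-05) lists were also called. Against controls 3 and 4 the ion channel (0.323), fibroblast (0.0676), macrophage (0.0867) and lymphocyte (0.0809) lists lost their calls, and the stress (0.0369) and neuronal (0.0307) lists were also called. With the Y-linked covariate the ion channel (0.103) and lymphocyte (0.0561) lists lost their calls and the neuronal list (0.0463) was called. Without KO 2 and control 2 the ion channel (0.0703), fibroblast (0.0719), macrophage (0.0719), lymphocyte (0.101) and interferon (0.101) lists lost their calls, and the stress (0.0437), neuronal (0.00673) and erythroid (0.00503) lists were also called. Against controls 3 and 4 alone 1700 genes were higher, with fewer samples in the fit. A stricter criterion left 477 higher and 275 lower beyond 1.5-fold by glmTreat, and 703 and 353 of at least 2-fold. The list of the skeletal muscle program had an adjusted p of 2.07e-06 with the direction up without KO 1, of 0.24 with the direction down without KO 2, and of 0.293, also down, without KO 2 and control 2. Differences that were not called turned sign: with single libraries left out, Cfd ranged from -0.40 to 4.18, Cidec from -0.55 to 3.95 and Plin1 from -0.46 to 3.25, each lowest without KO 4, and limma-voom gave -0.94 for Cidec and -0.25 for Plin1. Against controls 3 and 4, Ddx3y, Kdm5d, Uty and Eif2s3y were at -0.29, -0.39, -0.47 and -0.51, and with the covariate Uty and Eif2s3y at -0.04 and -0.12; both controls of that pair express Y-linked genes. The cause was not tested for the others. By fry the interferon (0.0523) and macrophage (0.0592) lists lost their calls, and the integrated stress response (0.0338) and lung and thymus (0.0366) lists were called. With an estimated correlation 15 lists lost their call and 14 were unchanged in call. Depth limited genes near the floor of 0.0744 to 0.0885 CPM.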

Other observations

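The gene families and single genes in this part were chosen after their values were seen, and the families were tested after the result was seen. In 3 families of protein synthesis and turnover more genes were called lower than higher in KO, though most members were not called. Of 77 mitochondrial ribosomal protein genes, 31 fell and 3 rose (median -0.20, camera adjusted p = 4.57e-06, adjusted p = 0.976 with an estimated correlation), with Mrpl23 at 19.5 ± 2.56 CPM in KO and 40.9 ± 0.924 CPM in control. Of 82 cytosolic ribosomal protein genes 18 fell and 0 rose by edgeR (median -0.13, camera adjusted p = 0.000487), and of 48 proteasome genes 18 fell and 1 rose (median -0.15, camera adjusted p = 0.016), both with adjusted p = 0.976 with an estimated correlation. The 13 mitochondrially encoded mRNAs had 0 calls by edgeR (median 0.07, camera adjusted p = 0.883). Mb, which encodes the oxygen store myoglobin, fell 3.25-fold, from 3669 to 1127 CPM (adjusted p = 1.47e-07).

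Of 22 adhesion G protein-coupled receptor genes, 10 rose and 0 fell by edgeR (median 0.41, camera adjusted p = 1.63e-05, adjusted p = 0.0539 with an estimated correlation). Adgrf3 rose from 0.5 ± 0.268 to 11.2 ± 1.32 CPM and Adgrb2 from 15.5 ± 2.40 to 50.1 ± 3.13 CPM. Aldehyde dehydrogenase genes went both ways, with 6 of 20 higher and 4 lower (median 0.16, camera adjusted p = 0.883). Aldh1l1 rose from 2.30 ± 0.594 to 29.3 ± 2.88 CPM (adjusted p = 5.71e-08) and Aldh1b1 fell from 114 ± 9.67 to 17.9 ± 2.35 CPM (adjusted p = 1.91e-08). Of 69 potassium channel genes 17 rose and 14 fell (median 0.06, camera adjusted p = 0.782), and of 353 Zfp zinc finger genes 32 rose and 21 fell (median 0.02, camera adjusted p = 0.99).

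Among genes with a mean under 0.1 CPM in control, 71 of 72 tested were called higher in KO, while 9 of 9 with a mean under 0.1 CPM in KO were called lower. A gene with so few counts in a group passes the filter by its counts in the other, so the share called is set by the filter and only the numbers of genes compare. The largest of them by KO level was Gm15398, a long non-coding RNA gene, with 2267 counts in KO and 1 in control, and Cdhr5, a cadherin-related gene, had 175 and 0.

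Some transcripts of neurons were near 0 in KO 2 and control 2 alone, while others were not. Syt1 was at 0.02 CPM in KO 2 and 0 in control 2 against 1.69 to 2.74 in the other KO and 4.89 to 4.98 in the other control libraries, and Snap25 and Grin2b were at 0.05 CPM or less in both, but Slc17a7 was at 213 and 136 CPM and Camk2a at 44.3 and 51.9 CPM in KO 2 and control 2. Of 13 central nervous system genes 2 were called higher and 0 lower by edgeR (median -0.31), and of 7 peripheral nerve genes 1 higher and 1 lower (median 0.13), where Ret fell by 1.47 on the log2 scale. Xist was at 395 CPM in KO 2, 408 in control 1 and 397 in control 2, with Ddx3y under 1 CPM in these 3 libraries. KO 3 held both Xist (30.4 CPM) and Ddx3y (108 CPM), while the other 4 libraries held Xist at 0.27 to 3.49 CPM and Ddx3y at 105 to 124 CPM.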
